A study of Bifidobacterium longum subsp. infantis with 32 samples.

How the data were processed

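RNA was sequenced from 4 strains of Bifidobacterium longum subsp. infantis, a bacterium of the infant gut, each grown on 4 sugars with 2 libraries per strain and sugar, 32 libraries in all. The strains were ATCC15697 and the isolates UMA299, UMA300 and UMA301. Per the labels' protocols, cells were kept anaerobically at 37 °C in MRS broth with 0.05% cysteine hydrochloride and moved to a version of the broth without its sugar, to which lactose (LAC), lacto-N-tetraose (LNT), lacto-N-neotetraose (LNnT) or pooled human milk oligosaccharides (HMO) was added. The labels give 2% (w/v) beside lactose, and it is not clear from them whether that figure holds for the other 3 sugars. Total RNA was treated with DNase, ribosomal RNA was removed with probes and libraries were made with a directional kit, per the labels' protocols.

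The authors deposited 1 table per strain, with 1 line per assembled transcript and 1 column per library. Values in the deposited tables are expected counts, estimates of the reads from each transcript that need not be whole numbers: 35.2 to 38.6 percent of the values per table were not whole. The submitters' processing notes name Bowtie2 2.3.4.3, RSEM 1.3.3, edgeR without a version, and R 3.6.2 and 3.4.0, with no role or order. Line names have the form that the Trinity assembler gives (gene, then isoform), so each table rests on its own assembly. The assembler's settings, a genome build and the normalization before deposit are not given in the sources used here, and the totals differed between libraries as unnormalized values do. Columns were matched to samples by the sample titles, and no column was left without a sample.

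The tables pair no transcript with a gene name. None of the 14177 lines (0) matched an identifier of the reference table of 2665 genes, so the gene lists fixed in advance (genes of oligosaccharide transport and breakdown among them), the tests of those lists and the always-named genes could not be applied, and transcripts are given by the identifiers of the files. The tables share 1976 to 2591 line names per pair of strains, but the mean log2 CPM of equal names correlated at r = 0.167 to 0.228 across transcripts, against 0.955 to 0.981 between replicate libraries. Equal names were therefore not treated as the same gene, and the planned test of whether the response to a sugar differed between strains was not run.

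Total expected counts ran from 4371537 to 7791696 per library, and the 10 most abundant transcripts held 17.3 to 36.3 percent of a library. A count of 3, used as the floor for a transcript with no reads, came to 0.385 to 0.686 CPM, the usual scale of counts by library size. Floors and bounds cover counting error only, since PCR copies were not separated. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 10.9 to 571), so each library counted as 1 replicate. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

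Expected counts were rounded to whole numbers. Transcripts were kept with edgeR's filterByExpr by group, which left 1506 in ATCC15697, 1254 in UMA299, 1566 in UMA300 and 1378 in UMA301, holding 99.97 to 99.98 percent of the counts of a strain. TMM factors ran from 0.855 to 1.14. For each strain 1 model was fitted to its 8 libraries (edgeR 4.0.16 quasi-likelihood F test, R 4.3.3, 4 residual degrees of freedom), and LNT, LNnT and HMO were each compared with lactose, and LNT with LNnT. Changed means a Benjamini-Hochberg adjusted p under 0.05 over the transcripts tested in that contrast. Fold changes are fitted log2 values. Their standard error (SE) was derived from the test, as the size of the log2 change over the square root of F. The 95 percent intervals rest on that derived SE. Levels are TMM-scaled CPM as mean ± SD of 2 libraries. The distance between 2 libraries is the root mean square difference of log2 CPM over the transcripts tested (prior count of 2), with the replicate part taken out, where stated, by subtracting the mean squared replicate distance of the 2 groups.

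Transcripts were named by a rule fixed in advance: largest rise and largest fall among those changed, with a mean log2 CPM of at least 4 and no overlap between replicates, 5 each against lactose and 3 each between LNT and LNnT where a gene name exists, and at most 2 each where only an identifier does. The rule took 64 transcripts at 2 each, 63 of them with no reads in 1 of the groups, and 15 of the 64 changed under 2-fold once the isoforms of their assembled gene were summed. The report gives at most 1 rise and 1 fall per contrast from these, taken from the 40 that were the single isoform of their gene or from genes whose sum moved alike, and for each contrast 1 rise and 1 fall with the largest change in CPM among the changed transcripts. That second rule and the choice within the first were made after the values were seen. A group without reads had expected counts that rounded to 0 in each library. Being the single isoform of a gene does not guard against reads taken by a redundant contig of another assembled gene. A fold against a group without reads is a lower bound on the fold of the means. It sets the mean of the group with reads against 3 counts per library in the other. The lower replicate of the group with reads alone can give a smaller fold.

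In simulated counts with the strains' lactose means, spreads and library sizes, 200 transcripts were changed in LNT against lactose. They were drawn from those with a lactose mean of at least 5 CPM, so recovery below that level is not known. Of 100 changed 2-fold, the test recovered 56 in ATCC15697, 27 in UMA299, 63 in UMA300 and 48 in UMA301. Of 100 changed 4-fold it recovered 87, 75, 90 and 82 in the same order, with 4 false calls among 147, 106, 157 and 134. The counts were drawn with the spread that edgeR fitted and tested with the same method. These rates therefore do not show how well that method describes the real libraries. For responses that share the lactose libraries, 20 simulations per strain of groups all at the lactose mean gave values for comparison. Transcripts without lactose reads had no reads in these simulations.

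The rule for naming transcripts and these alternatives were fixed before the data were examined: DESeq2 size factors in the same fit, total counts without a composition factor, no filter on low counts, the replicate number as a block, the DESeq2 1.42.0 Wald test, the spread from the 2 groups compared and leaving out each library in turn. Summing isoforms to the assembled gene, a mean of at least 5 CPM, and prior counts of 0.5 and 5 for the distances were added after seeing the data. With total counts in place of TMM factors, the median log2 change over all tested transcripts moved to 0.36 for LNT and 0.62 for LNnT in UMA299, to -0.30 for HMO in UMA301 and to -0.21 for HMO in UMA300. Without the filter it moved to -0.29 for LNT and -0.60 for HMO in ATCC15697 and to -0.48 for LNnT and -0.64 for HMO in UMA301. In the fit used for the report, with the filter, TMM factors and all libraries, the largest median in size was 0.22, for LNnT in UMA299.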

Results

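Transcript abundance was measured in 4 strains of Bifidobacterium longum subsp. infantis growing on lactose, on the tetrasaccharides lacto-N-tetraose (LNT) and lacto-N-neotetraose (LNnT), or on pooled human milk oligosaccharides (HMO), the mixture of sugars in milk from which this bacterium draws carbon in the infant gut. Each of the 16 combinations of strain and sugar had 2 libraries, with totals of 4371537 to 7791696 expected counts. The design asks how the transcriptome of each strain differs between growth on milk oligosaccharides and growth on lactose, and whether the strains use these sugars differently. Transcripts bear assembly identifiers without gene names, so groups of transcripts are described by the sugars on which they moved. Replicate libraries correlated at r = 0.955 to 0.981 across transcripts.

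In ATCC15697, growth on HMO changed 656 of 1506 transcripts against lactose, of which 274 rose and 382 fell, with a median change of 2.303-fold among them. LNT changed 370 (193 up, 177 down) and LNnT changed 258 (145 up, 113 down), with medians of 2.13-fold and 1.83-fold. TRINITY_DN100_c0_g1_i3 had the largest fall by CPM among the changed transcripts on each of the 3 sugars, from 47828 ± 11055 CPM (SD, n = 2) on lactose. It stood at 5089 ± 1247 CPM on LNT (log2 change -3.23, SE 0.22), at 15131 ± 153 CPM on LNnT (-1.66, SE 0.21) and at 190 CPM on HMO, where it was 252-fold lower (-7.98, SE 0.27, edgeR adjusted p = 1.7e-05). TRINITY_DN188_c0_g1_i1 moved the other way, from 1587 ± 22.8 CPM on lactose to 10759 ± 319 CPM on HMO, a 6.78-fold rise (edgeR adjusted p = 7.3e-06), and it stood at 7807 CPM on LNT and 8437 CPM on LNnT. TRINITY_DN235_c1_g1_i3 rose 2.41-fold on LNT, to 29644 ± 2721 CPM, and 1.61-fold on LNnT, where leaving out LAC replicate 2 or either LNnT library ended the call.

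Other transcripts of ATCC15697 had reads on 1 sugar and none on another. Here and in the other strains, no reads means expected counts that rounded to 0. Reads taken by a redundant contig of another assembled gene cannot be told apart from a change in expression for such transcripts. TRINITY_DN319_c0_g2_i1 had no reads on lactose, 220 ± 2.51 CPM on LNT, which is at least 544-fold higher, and 48.9 ± 24.4 CPM on LNnT, at least 121-fold higher. On HMO it stood at 83.5 ± 31.6 CPM. TRINITY_DN118_c0_g1_i1 had reads on HMO (350 ± 22.3 CPM) and none on lactose, at least 867-fold higher. TRINITY_DN1419_c0_g1_i1, at 98.1 ± 20.1 CPM on lactose, had no reads on LNT, LNnT or HMO and was at least 188-fold and 227-fold lower on LNT and LNnT. Across the 3 sugars, 40 transcripts rose on all of them and 21 fell on all of them (6 without LAC replicate 2). The 40 held 3.47 percent of the lactose libraries and 7.24 percent of the HMO libraries, and the 21 held 7.20 percent and 0.638 percent. Both groups were chosen by these same calls, so their shares follow in part from the choice. A further 142 rose and 219 fell on HMO while passing the test on neither tetrasaccharide. The count of changed transcripts depended on single libraries: without any 1 of the 4 libraries compared it was 150 to 224 for LNT and 122 to 159 for LNnT, and without 1 of the lactose libraries it was 428 or 397 for HMO. The share of rises among changed transcripts turned with the settings: 52.2 percent on LNT (41.3 with DESeq2 size factors, 37.1 with total counts, 64.1 without the filter), 56.2 percent on LNnT (42.9 with total counts) and 41.8 percent on HMO (55.9 without the filter).

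In UMA299, more transcripts passed the test on each tetrasaccharide than on the pooled oligosaccharides. LNT changed 594 of 1254 transcripts (311 up, 283 down) and LNnT changed 687 (358 up, 329 down), with median changes of 3.05-fold and 3.78-fold, whereas HMO changed 50 (27 up, 23 down). A group of 185 transcripts that rose on both LNT and LNnT and did not pass the test as a rise on HMO (183 did not pass it and 2 fell) took 10.5 percent of the lactose libraries, 28.2 percent on LNT, 35.03 percent on LNnT and 12.5 percent on HMO. A group of 204 that fell on both and did not pass the test as a fall on HMO (201 did not pass it and 3 rose) took 49.7 percent on lactose, 25.4 percent on LNT, 20.3 percent on LNnT and 44.2 percent on HMO. Both groups were chosen by these same calls, so their shares follow in part from the choice. HMO was not tested against LNT or LNnT. Of the 1204 transcripts that did not pass the test on HMO, the 95 percent interval reached 2-fold for 725. TRINITY_DN2_c0_g1_i1 had the largest fall by CPM, from 80736 ± 33091 CPM on lactose to 456 ± 8.70 on LNT, 177-fold lower (log2 -7.47, SE 0.55, edgeR adjusted p = 0.00029), and to 1036 ± 79.5 on LNnT, 77.9-fold lower (edgeR adjusted p = 0.00028). On HMO it held 33379 ± 17448 CPM. This transcript is in the group of 204, and its replicates were far apart on lactose and on HMO. TRINITY_DN132_c1_g1_i1 rose 5.92-fold on LNnT, from 7216 ± 536 to 42734 ± 6443 CPM (edgeR adjusted p = 7.8e-05), and TRINITY_DN20_c0_g3_i1 rose 1.69-fold on LNT, to 55393 ± 2799 CPM.

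Some UMA299 transcripts had reads on 1 of the sugars compared and none on the other. TRINITY_DN2269_c0_g1_i1, at 269 ± 66.1 CPM on lactose, had none on LNT or LNnT and was at least 649-fold and 636-fold lower. On HMO it stood at 53.3 ± 47.8 CPM. TRINITY_DN35_c1_g1_i1 had 145 ± 16.3 CPM on LNT (at least 250-fold higher than lactose) and TRINITY_DN298_c0_g1_i1 had 424 ± 106 CPM on LNnT (at least 731-fold higher). The first stood at 63.3 ± 9.41 CPM on LNnT and the second at 51.1 ± 32.5 CPM on LNT. On HMO, TRINITY_DN112_c0_g1_i1 fell 1.80-fold, from 43639 ± 5260 to 24257 ± 2004 CPM (edgeR adjusted p = 0.030), and TRINITY_DN936_c0_g1_i1 rose 1.89-fold, to 16979 ± 952 CPM (edgeR adjusted p = 0.045). TRINITY_DN280_c0_g1_i1 was at least 119-fold higher on HMO than on lactose (69.2 ± 36.9 CPM against no reads). TRINITY_DN941_c0_g1_i1 was at least 114-fold lower on HMO than on lactose, and it had no reads on LNT or LNnT either. The HMO count was 0 without either HMO library, 12 without LAC replicate 1 and 28 without LAC replicate 2, and 0 with the spread of the 2 groups alone. The DESeq2 Wald test called 187, and 288 transcripts had an unadjusted p under 0.05 in edgeR. The 4 HMO transcripts named here lost their call in all or most of the fits without 1 library and with the spread of the 2 groups alone, TRINITY_DN280_c0_g1_i1 also with the DESeq2 Wald test and TRINITY_DN936_c0_g1_i1 also with DESeq2 size factors. The share of rises was 52.4 percent on LNT, 52.1 percent on LNnT and 54.0 percent on HMO, against 65.4, 65.1 and 67.3 percent with total counts, 48.1 and 47.1 percent on LNT and LNnT with the DESeq2 Wald test, and 41.8 percent on HMO with DESeq2 size factors.

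In UMA300, each of the 3 sugars changed a large part of the transcriptome. LNT changed 526 of 1566 transcripts (308 up, 218 down), LNnT changed 644 (312 up, 332 down) and HMO changed 664 (336 up, 328 down), with median changes of 2.57-fold, 2.38-fold and 2.40-fold. A set of 64 transcripts rose and 76 fell on all 3 sugars (45 falls without LNT replicate 1), and 128 rose and 107 fell on HMO without passing the test on either tetrasaccharide. TRINITY_DN68_c1_g2_i3 rose 2.17-fold on LNT, from 28114 ± 7092 to 60956 ± 2850 CPM (edgeR adjusted p = 0.0073, 0.0502 without LNT replicate 1). TRINITY_DN2271_c0_g1_i1 fell 1.72-fold on LNT and 2.77-fold on LNnT, from 27375 ± 1105 to 15909 ± 1005 and 9887 ± 1313 CPM. TRINITY_DN2_c1_g7_i1 rose 4.37-fold on LNnT, from 7524 ± 1616 to 32849 ± 4328 CPM (log2 2.13, SE 0.19, edgeR adjusted p = 0.00030), and with the 2 isoforms of its gene summed the log2 change was 1.18. On HMO, TRINITY_DN79_c1_g1_i2 rose 1.86-fold, to 56579 ± 2573 CPM, and TRINITY_DN180_c0_g1_i1 fell 5.68-fold, from 16222 ± 493 to 2858 ± 360 CPM (edgeR adjusted p = 7.4e-05).

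Among UMA300 transcripts with reads on 1 sugar and none on another, TRINITY_DN104_c0_g2_i9 had none on lactose, 248 ± 6.81 CPM on LNT and 666 ± 282 CPM on HMO, at least 500-fold and 1342-fold higher, and the sum over the 10 isoforms of its gene rose on both too. On LNnT the transcript stood at 537 ± 3.52 CPM. TRINITY_DN2552_c0_g1_i1, at 177 ± 2.06 CPM on lactose, had no reads on LNnT or HMO and was at least 416-fold and 314-fold lower. TRINITY_DN125_c0_g1_i1 had 426 ± 3.32 CPM on lactose and none on LNT, at least 884-fold lower. It stood at 0.50 ± 0.71 CPM on LNnT and 5.68 ± 8.03 CPM on HMO. Leaving out either LNT library lowered the LNT count to 238 (without replicate 1) or 304 (without replicate 2). The share of rises turned with the settings: 58.6 percent on LNT (37.8 without the filter), 48.4 percent on LNnT (53.2 at a mean of at least 5 CPM) and 50.6 percent on HMO (40.5 with total counts).

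In UMA301, fewer transcripts passed the test on LNT than on the other sugars. LNT changed 80 of 1378 transcripts (60 up, 20 down), LNnT changed 539 (246 up, 293 down) and HMO changed 652 (288 up, 364 down), with median changes of 2.75-fold, 2.95-fold and 3.16-fold. TRINITY_DN8_c0_g1_i3 fell from 31860 ± 1668 CPM on lactose to 713 ± 441 on LNnT, 44.7-fold lower (log2 -5.48, SE 0.55, edgeR adjusted p = 0.0011), and to 134 ± 7.41 on HMO, 238-fold lower (log2 -7.89, SE 0.61, edgeR adjusted p = 0.00032). On LNT it held 14011 ± 5690 CPM. A second isoform of the same assembled gene, TRINITY_DN8_c0_g1_i2, had 12609 ± 977 CPM on lactose and no reads on LNnT or HMO, at least 27430-fold and 25713-fold lower, and with its isoforms summed the gene's log2 change was -5.94 on LNnT and -8.33 on HMO. TRINITY_DN1511_c0_g1_i1 rose 8.54-fold on LNnT, from 1124 ± 36.3 to 9594 ± 1099 CPM (edgeR adjusted p = 1.5e-05), and stood at 7795 ± 359 CPM on LNT and 12273 ± 497 CPM on HMO. TRINITY_DN9_c0_g1_i2 rose 1.73-fold on HMO, to 62373 ± 1461 CPM.

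TRINITY_DN1850_c0_g1_i1 had no reads on lactose in UMA301, 236 ± 66.9 CPM on LNnT and 257 ± 33.8 CPM on HMO, at least 523-fold and 568-fold higher. On LNT, TRINITY_DN26_c0_g1_i2 rose 1.49-fold to 32506 ± 2876 CPM (edgeR adjusted p = 0.022) and TRINITY_DN15_c0_g1_i1 fell 1.32-fold to 1414 ± 19.4 CPM (edgeR adjusted p = 0.019), and the first lost its call in 3 of the 4 fits without 1 library and the second in all 4 and without a filter. TRINITY_DN2140_c0_g1_i1, at 182 ± 2.29 CPM on lactose, had no reads on LNT, LNnT or HMO and was at least 384-fold lower on LNT. TRINITY_DN2184_c0_g1_i1, with none on lactose, had 25.0 ± 3.75 CPM on LNT, at least 55.4-fold higher, a call that ended in all 4 fits without 1 library. It stood at 11.7 ± 12.6 CPM on LNnT and 59.1 ± 2.09 CPM on HMO. Of the 80 transcripts changed on LNT, 37 rose and 10 fell on all 3 sugars. Both counts were lower without a lactose library and higher without an LNnT library. Those fits make their own LNT calls, so their counts are not parts of the 80. The LNT count was 27 to 33 without any 1 of the libraries compared, 170 with the DESeq2 Wald test and 206 with the spread of the 2 groups alone. The LNnT count was lower without either lactose library or LNnT replicate 1, and higher without LNnT replicate 2. The HMO count was lower without any 1 of the lactose or HMO libraries. The share of rises was 75.0 percent on LNT (56.8 with total counts), and it turned with the settings on LNnT, from 45.6 to 54.4 percent without the filter, and on HMO, from 44.2 to 54.3 percent at a mean of at least 5 CPM (31.99 with total counts).

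**Figure D1:**
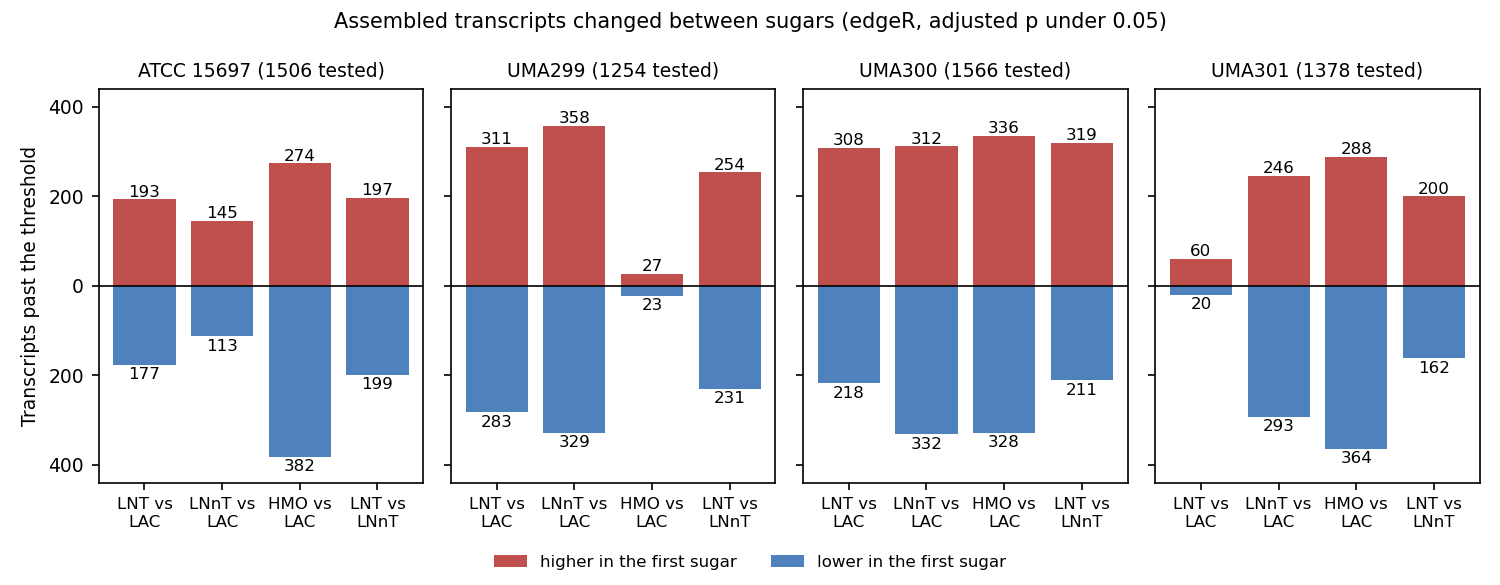
Number of assembled transcripts (vertical axis) past an adjusted p of 0.05 in edgeR, for each strain and pair of sugars, with transcripts higher in the first sugar above 0 and those lower in it below 0. HMO against lactose gives 656, 50, 664 and 652 changed transcripts in ATCC15697, UMA299, UMA300 and UMA301.

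The distances between libraries gave an account of the same responses that does not rest on a threshold. In ATCC15697, HMO lay 2.17 from lactose (mean of 4 library pairs, 2.14 to 2.20), LNT 1.67 (1.58 to 1.79) and LNnT 1.44 (1.40 to 1.47), with replicates 0.875 to 1.05 apart. In UMA299, HMO lay 1.59 from lactose (1.52 to 1.65), LNT 2.53 (2.50 to 2.57) and LNnT 2.79 (2.76 to 2.86), and the lactose replicates were 1.25 and the HMO replicates 1.28 apart. In UMA300 the distances were 2.37 (2.31 to 2.43) for HMO, 2.02 (1.97 to 2.05) for LNT and 2.12 (2.07 to 2.19) for LNnT. In UMA301 they were 2.44 (2.42 to 2.48), 1.40 (1.302 to 1.47) and 2.297 (2.15 to 2.45). The LNnT replicates of UMA301 were 1.23 apart, against 0.785 on lactose, 0.989 on LNT and 0.828 on HMO. All 8 libraries of a strain share 1 estimate of the spread in the counts of changed transcripts. The library pairs of HMO and LNT did not overlap in any of the 4 strains, with HMO farther from lactose in ATCC15697, UMA300 and UMA301 and nearer in UMA299. The 4 library pairs of a contrast share libraries and are not independent, and no test of the difference between strains was run.

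**Figure D2:**
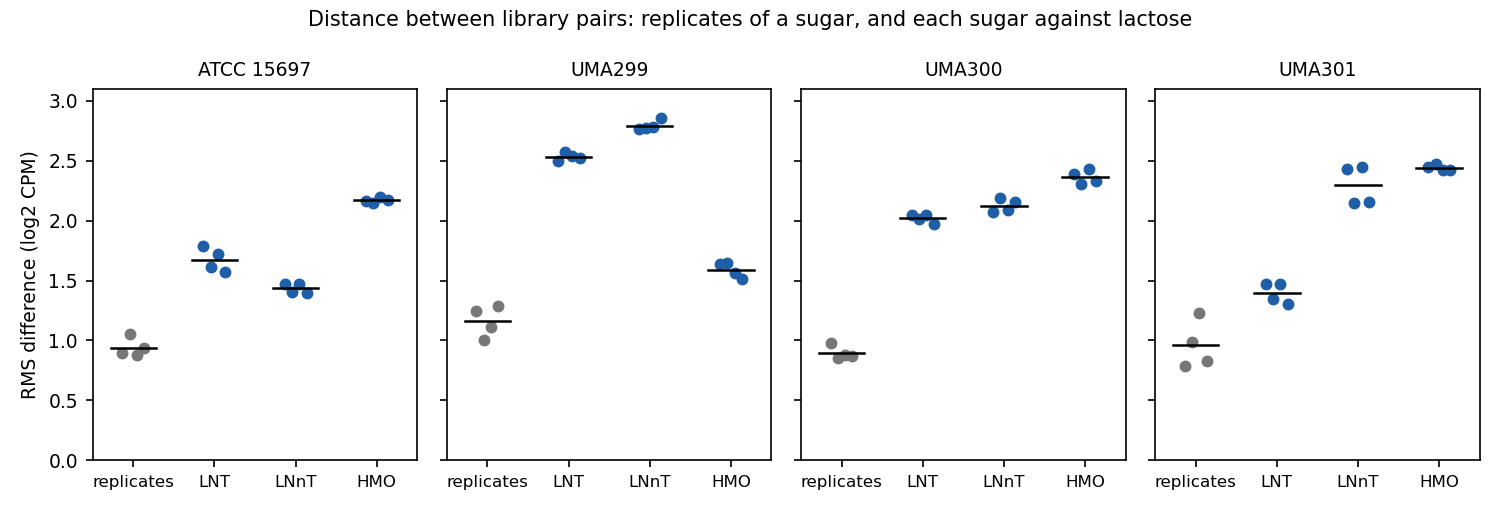
Root mean square difference of log2 CPM (vertical axis) between library pairs of each strain: grey points are the 4 pairs of replicates, blue points the 4 pairs of a library on LNT, LNnT or HMO with a lactose library, and bars the means. HMO lies above LNT in ATCC15697, UMA300 and UMA301 and below it in UMA299, where its mean is 1.59.

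LNT and LNnT are isomers built from the same sugars, and they differ in the linkage between the terminal galactose and N-acetylglucosamine. Whether both were given at the same concentration is not stated separately in the labels. In each strain their transcriptomes differed: 396 transcripts in ATCC15697 (197 higher on LNT, 199 lower), 485 in UMA299 (254 and 231), 530 in UMA300 (319 and 211) and 362 in UMA301 (200 and 162). Which isomer had more transcripts on its side turned with the settings in each strain, and without the filter the counts were 194 higher and 283 lower on LNT in UMA300 and 146 and 163 in UMA301. In ATCC15697, TRINITY_DN2713_c0_g1_i1 was 2.21-fold higher on LNT (23850 ± 1015 against 10770 ± 1125 CPM, edgeR adjusted p = 0.0033), and TRINITY_DN77_c0_g2_i1 had no reads on LNT and 286 ± 20.3 CPM on LNnT, at least 548-fold lower on LNT. TRINITY_DN100_c0_g1_i3 was 2.97-fold lower on LNT than on LNnT. In UMA299, TRINITY_DN25_c2_g1_i1 was 5.21-fold higher on LNT (20155 ± 1760 against 3868 ± 466 CPM, edgeR adjusted p = 0.00017), and TRINITY_DN53_c0_g1_i1 was 29.2-fold lower on LNT (1100 ± 382 against 32175 ± 2109 CPM, edgeR adjusted p = 0.012), a call that ended without either LNT library. In UMA300, TRINITY_DN795_c0_g1_i2 was 3.83-fold higher on LNT (25624 ± 2095 against 6687 ± 1292 CPM, edgeR adjusted p = 0.00069), and TRINITY_DN19_c0_g1_i1 had 656 ± 9.94 CPM on LNT and no reads on LNnT, at least 1538-fold higher. TRINITY_DN2_c1_g7_i1 was 3.36-fold lower on LNT (log2 -1.75, SE 0.18), and with isoforms summed the log2 difference was -0.74. In UMA301, TRINITY_DN8_c0_g1_i3 was 19.7-fold higher on LNT (14011 ± 5690 against 713 ± 441 CPM, log2 4.297, SE 0.52, edgeR adjusted p = 0.0044), and TRINITY_DN1_c0_g1_i1 was 1.58-fold lower on LNT (9803 ± 30.8 against 15500 ± 479 CPM, edgeR adjusted p = 0.0011).

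For many other transcripts the isomers were not told apart. Of those that did not pass the test, the 95 percent interval of the difference lay within 2-fold for 429 in ATCC15697, 207 in UMA299, 357 in UMA300 and 376 in UMA301, and it reached 2-fold or more for 649, 507, 614 and 594, for which a 2-fold difference cannot be excluded. The direction of the response to lactose was opposite on the isomers, with both passing the test, for 20 transcripts in ATCC15697, 27 in UMA299, 22 in UMA300 and 2 in UMA301. Without 1 library the number of transcripts that differed between the isomers was 152 to 225 in ATCC15697 (any of the 4 libraries). It was 258, 260 and 303 in UMA299 and 325, 301 and 312 in UMA300 without LNT replicate 1, LNT replicate 2 or LNnT replicate 2, and 130 or 76 in UMA301 without LNT replicate 1 or 2. In UMA301 the spread of the 2 groups alone gave 124.

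Responses to the 3 sugars within a strain share the lactose libraries and so correlate by chance. The log2 changes on LNT and LNnT correlated across transcripts at r = 0.343 in ATCC15697, 0.627 in UMA299, 0.646 in UMA300 and 0.517 in UMA301, against 0.487, 0.526, 0.517 and 0.473 in simulated groups without any effect. The covariance was 1.54, 9.25, 5.68 and 3.12, against 0.289, 0.485, 0.268 and 0.288 simulated. The simulations set each group to the lactose mean, so transcripts without lactose reads had none in them. The simulated values therefore do not measure what the shared lactose libraries add in these data. Transcripts that rose on both isomers numbered 77, 197, 151 and 48, where independent lists of the same lengths would share 18.6, 88.8, 61.4 and 10.7, values that leave out the shared lactose libraries. Those that fell on both numbered 35, 215, 154 and 16, against 13.3, 74.2, 46.2 and 4.25. For LNnT and HMO, r was 0.488 in ATCC15697, 0.286 in UMA299, 0.376 in UMA300 and 0.606 in UMA301, against 0.506, 0.496, 0.508 and 0.478 simulated, and the covariance was 3.12, 2.50, 4.02 and 6.99, against 0.301, 0.460, 0.262 and 0.286. For LNT and HMO, r was 0.314, 0.358, 0.383 and 0.436, against 0.505, 0.497, 0.506 and 0.474 simulated. The covariance was 2.23, 2.93, 3.80 and 2.89, against 0.301, 0.459, 0.260 and 0.290. In the simulations only noise and the shared lactose libraries set r. An observed r below the simulated one therefore does not show that 2 responses were less alike than without an effect. Rank correlations (Spearman) for LNT and LNnT were 0.360, 0.547, 0.566 and 0.600 in the same order of strains. For LNnT and HMO they were 0.457, 0.286, 0.072 and 0.574, and for LNT and HMO 0.204, 0.305, 0.185 and 0.463. In UMA300, 138 transcripts moved in opposite directions on LNnT and HMO, where independent lists would give 137, while 96 rose on both (66.9 expected) and 118 fell on both (69.5 expected). The 2 lactose libraries cannot be split into sets of 2, so part of the shared calls may come from them.

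**Figure D3:**
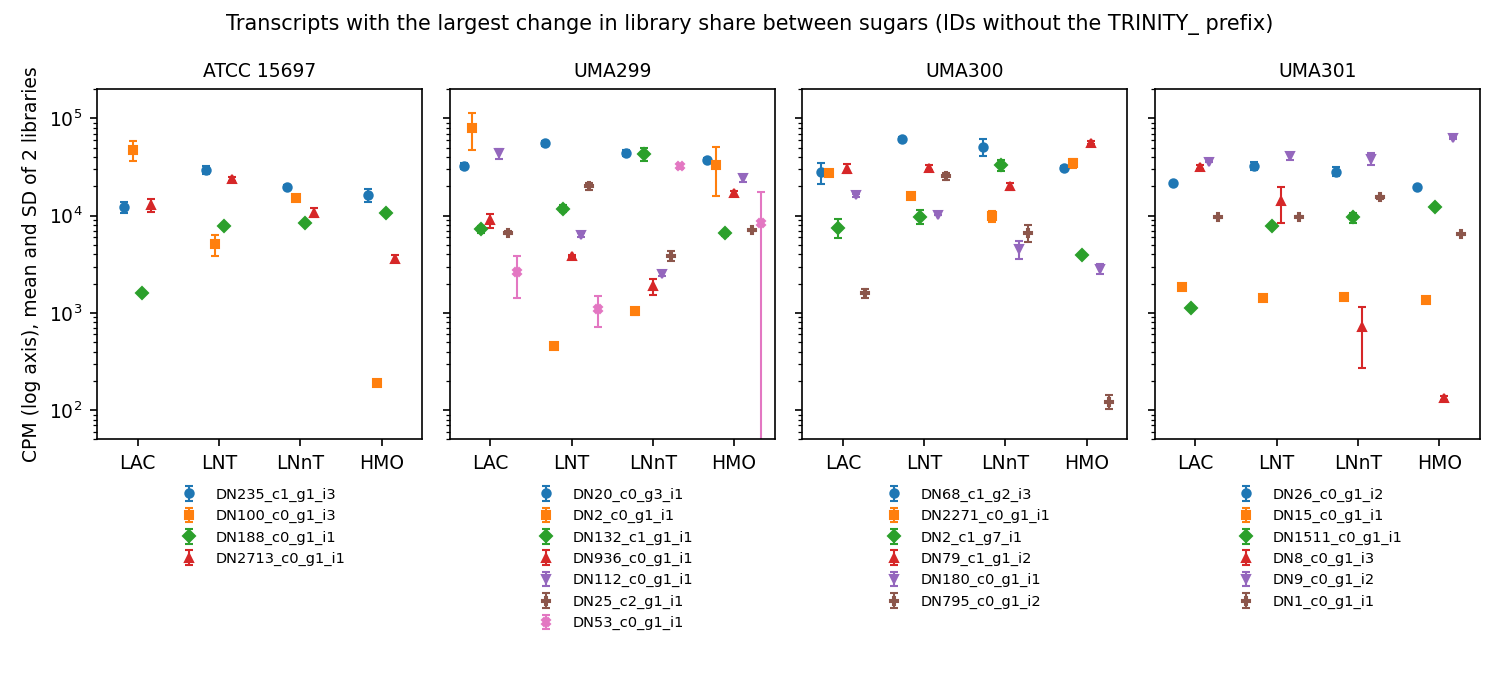
Abundance in CPM (log axis) of the transcripts with the largest rise or fall in library share between the sugars compared, per strain; points are means and bars SDs of 2 libraries, and 1 bar, of DN53_c0_g1_i1 on HMO in UMA299, reaches below the axis. DN100_c0_g1_i3 in ATCC15697 goes from 47828 CPM on lactose to 190 on HMO, and DN8_c0_g1_i3 in UMA301 from 31860 to 134.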

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

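The tests of the replicate spread, of an exchange of libraries, of cells growing on lactose, of isoforms and of redundant contigs in this part were chosen after the results were seen. The test at equal depth was chosen before its result was seen.

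The order of the sugars by their distance from lactose differed between strains. HMO minus LNT, in root mean square log2 CPM, was 0.496 in ATCC15697, 0.346 in UMA300 and 1.045 in UMA301, but -0.943 in UMA299, without overlap between the library pairs of the sugars in any strain. LNT minus LNnT was 0.237 in ATCC15697, -0.261 in UMA299, -0.105 in UMA300 and -0.899 in UMA301. In UMA300 the library pairs of these sugars overlapped with a prior count of 0.5 (LNT up to 2.660, LNnT from 2.657). They also overlapped with isoforms summed (LNT up to 1.983, LNnT from 1.953). Neither difference between strains was tested. Each group has 2 libraries, and the library pairs behind a distance share libraries.

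The small HMO response of UMA299 was weighed against 4 technical explanations. Depth is argued against: with all 8 libraries thinned to the total of the smallest, 35 transcripts changed on HMO and 590 on LNT. A wider spread between replicates is argued against as the whole cause: with the replicate part taken out, HMO lay 0.963 from lactose (0.833 to 1.05 over library pairs) and LNT 2.27 (2.23 to 2.31). An exchange of 1 HMO library with 1 lactose library is argued against too, since each of the 4 libraries correlated better with its partner than with the other sugar's libraries, by at least 0.018 in r, and since the exchange needs both crossed pairs to lie close: by chi-square per degree of freedom LAC 2 and HMO 2 were closer (253) than the lactose (545) and HMO (571) replicates, but LAC 1 and HMO 1 were farther (711). TRINITY_DN61_c0_g1, with isoforms summed, held 4817 and 76967 CPM in the lactose libraries and 4812 and 68590 on HMO. It was high in both LAC 2 and HMO 2 and enters these chi-square values, which were not computed without it. Both HMO libraries coming from cells that used lactose cannot be told apart from a weak response to HMO with 50 changed transcripts and 2 libraries per group. A strain difference in HMO use, which the design names, stays open and untested.

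A second pattern was 364 cases, over the 12 contrasts with lactose, of a changed transcript with at most 3 counts in each library of 1 sugar and at least 100 in each of the other. Assignment of reads to another isoform of the same assembled gene stays open in UMA300, where 4 of 51 cases in genes with several isoforms changed under 2-fold once isoforms were summed, but 18 of the 51 came from 1 gene. With each gene counted once, 4 of 16 genes (25 percent, exact binomial upper bound 52.4) did so in any of their cases and 3 in all of them, and in the other 3 strains 14 of 24 (58.3 percent, upper bound 77.9) in any and 11 (45.8 percent, lower bound 25.6) in all, so it stays open there too. For the 268 cases in genes with a single isoform, reads taken by a redundant contig of another assembled gene cannot be told apart from a switch in expression, because that needs the contig sequences, not used here.

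The third pattern was replicates of 1 group over 16-fold apart on a transcript with at least 50 CPM in 1 of them, 39 cases in all. In ATCC15697, UMA300 and UMA301, 14 of 15 genes with such cases and several isoforms (93.3 percent, exact binomial lower bound 68.1) fell under 2-fold once isoforms were summed. That leaves out the 4 of 21 cases there in genes with a single isoform (10 of the 39 in all). A sum also stays flat where other isoforms hold most reads of a gene, and opposite moves of other isoforms were not checked. Reads moving between isoforms of 1 gene therefore stay open as an explanation. In UMA299, 2 of 3 such genes (66.7 percent) fell under 2-fold once isoforms were summed, too few to decide, and 10 of the 12 cases came from 1 gene. The extreme case was TRINITY_DN61_c0_g1, a gene of 9 isoforms whose sum, scaled with the TMM factors of the table of summed isoforms, was 4817 and 76967 CPM in the lactose libraries, 2237 and 17349 on LNT, 5427 and 916 on LNnT and 4812 and 68590 on HMO. Leftover RNA from the removal of ribosomal RNA and a difference between cultures both stay open for it, since its sequence was not used here.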

How the results depend on the processing

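The alternatives listed as added in the processing summary, and all fits of the transcripts chosen by CPM, were chosen after seeing the data. The counts of changed transcripts in the 16 contrasts stayed within 1.5 times under DESeq2 size factors, total counts, no filter, summed isoforms and a mean of at least 5 CPM. For HMO in UMA299 (50) the DESeq2 Wald test gave 187 and the spread of the 2 groups alone 0. For LNT in UMA301 (80) these gave 170 and 206, and for LNT against LNnT in UMA301 (362) the spread of the 2 groups alone gave 124. The cause was not tested. Same-numbered replicates deviated together at r = -0.229 to 0.199, above 0.1 in 5 of 24 pairs of sugars. These values do not show that the numbers pair the libraries, and they do not exclude a shared effect for some sugars. In UMA299 r was 0.186 for lactose with LNT, 0.199 for LNT with HMO and 0.053 for lactose with HMO. It was -0.229 to -0.079 for LNnT with the other sugars. With the replicate number as a replicate block the HMO count in UMA299 was 0, and the other 15 counts stayed within 1.5 times.

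Leaving out 1 library leaves a lone library that is assumed to vary like the other groups, and takes 1 residual degree of freedom. For the counts of a contrast, only libraries of the 2 groups compared were left out. For LNT, LNnT and HMO against lactose and LNT against LNnT the counts were then 150 to 224, 122 to 159, 397 to 547 and 152 to 225 in ATCC15697. In UMA299 they were 412 to 491, 509 to 556, 0 to 28 and 258 to 363, in UMA300 238 to 360, 446 to 517, 474 to 557 and 301 to 403, and in UMA301 27 to 33, 194 to 633, 299 to 390 and 76 to 514. The 633 and the 514 came without LNnT replicate 2 of UMA301, and the cause was not tested.

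Transcripts that rose on all 3 sugars numbered 32 to 54 in ATCC15697 (40), 0 to 40 in UMA299 (12), 49 to 79 in UMA300 (64) and 24 to 55 in UMA301 (37) over the settings with all libraries, and those that fell 12 to 35 (21), 0 to 50 (11), 63 to 94 (76) and 6 to 34 (10). Without 1 library the rises numbered 29 to 44, 0 to 8, 45 to 61 and 17 to 70 and the falls 6 to 21, 0 to 8, 45 to 67 and 4 to 31, in the same order. Whether more transcripts rose than fell turned under at least 1 setting with all libraries, the block aside, in 15 of the 16 contrasts, and LNT in UMA301 was the exception (56.8 to 76.4 percent rises). Correlations moved as follows: LNT with HMO in ATCC15697 to 0.50002 without the filter and 0.253 at 5 CPM, LNT with LNnT in UMA299 to 0.570 without it, LNT with HMO in UMA300 to 0.312 with summed isoforms and 0.521 at 5 CPM, LNnT with HMO in UMA300 to 0.303 with summed isoforms, and LNnT with HMO in UMA301 to 0.673 without the filter and 0.558 at 5 CPM. Without 1 library LNT with LNnT ran from 0.312 to 0.475 in ATCC15697 and from 0.384 to 0.563 in UMA301, and LNT with HMO in ATCC15697 rose to 0.380 without LAC replicate 1 and 0.405 without LAC replicate 2.

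HMO minus LNT in distance from lactose kept its direction in each strain over the 5 other settings: 0.387 to 0.683 in ATCC15697, -1.12 to -0.828 in UMA299, 0.317 to 0.480 in UMA300 and 0.869 to 1.33 in UMA301. Of the 64 transcripts taken by the rule, 6 changed sign when isoforms were summed: log2 -0.24 (LNT), 0.0348 (LNnT) and 0.52 (HMO) in ATCC15697, 0.32 (LNT) in UMA299, -1.55 (LNnT) in UMA300 and 0.0912 (LNnT) in UMA301. Summing counts other isoforms of the gene, which is the cause by construction. Another 2 lost their call then, 6 under the block, 5 with the spread of 2 groups, 1 with DESeq2 and 36 of 256 fits without 1 library. Of the 32 chosen by CPM none changed sign, and 20 of 128 fits without 1 library lost the call. The planned test of strain differences and the gene list tests were not run. Depth limits transcripts near 0.385 to 0.686 CPM. The self-test recovered 27 of 100 changes of 2-fold in UMA299, among transcripts with a lactose mean of at least 5 CPM.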

Other observations

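Values of some abundant transcripts on the 4 sugars were as follows. TRINITY_DN188_c0_g1_i1 of ATCC15697 stood at 1587, 7807, 8437 and 10759 CPM on lactose, LNT, LNnT and HMO, and TRINITY_DN1511_c0_g1_i1 of UMA301 at 1124, 7795, 9594 and 12273. TRINITY_DN100_c0_g1_i3 of ATCC15697 stood at 47828, 5089, 15131 and 190 CPM, and TRINITY_DN8_c0_g1_i3 of UMA301 at 31860, 14011, 713 and 134. TRINITY_DN132_c1_g1_i1 of UMA299 reached 42734 CPM on LNnT against 7216 on lactose, and TRINITY_DN2_c1_g7_i1 of UMA300 reached 32849 against 7524. TRINITY_DN795_c0_g1_i2 of UMA300 ranged from 122 ± 19.8 CPM on HMO to 25624 ± 2095 on LNT. These were picked after their values were seen, and whether any of them are the same gene was not tested.

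The number of transcripts with at least 1 count differed between sugars with the 8 libraries of a strain thinned to the same total. In ATCC15697 it was 2371 and 2456 on lactose, 2175 and 2193 on LNnT, 1822 and 1848 on LNT, and 1612 and 1633 on HMO. In UMA301 it was 2192 and 2142 on lactose, 1872 and 2036 on LNT, 1401 and 1477 on LNnT, and 1406 and 1377 on HMO. In UMA300 LNT had 2268 and 2206, lactose 1635 and 1695, LNnT 1899 in each, and HMO 1570 and 1544. In UMA299 LNnT had 1624 and 1622 and the libraries of the other sugars 1306 to 1541. No explanation was tested.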
